A study of Mus musculus with 9 samples.

How the data were processed

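Nuclei were isolated from mouse brown adipose tissue in 3 groups of 3 libraries: a normal diet (ND), a high-fat diet (HFD), and a high-fat diet with dihydromyricetin at 200 mg/kg (DHM_HFD). Per the labels, nuclei were stained with propidium iodide and sorted, loaded for the 3' v3 kit of 10x Genomics and sequenced on a NovaSeq. The length of the diets, the route of the compound, the sex of the mice and the time of day at collection are not given. Replicates are numbered 1 to 3 in each group. The labels do not say whether each library comes from a separate mouse, so every p-value here measures the spread between these samples. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 7.2.0 on mm10 according to the submitters' processing notes. All 9 use the same list of 55357 genes, every value is a whole number, and no barcode has fewer than 500 UMIs. The annotation release, the treatment of intronic reads and any further filter are not stated. Of the gene IDs, 52081 are found in GENCODE M21, which gave the positions on GRCm38 printed here, matched by ID. It may not be the release the authors used.

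The libraries hold 8981 to 17773 barcodes, 104381 in all, and 47959889 to 54401107 UMIs each. Since the totals are alike, the libraries with the most barcodes are the shallowest: HFD replicate 1 has 15402 barcodes and a median of 2807 UMIs, and DHM_HFD replicate 3 has 17773 and 2651, against medians of 4133 to 5235 UMIs in the other 7. A gene at 10 CPM therefore rests on many UMIs per library in adipocyte nuclei and on few in the classes with few nuclei.

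Filters were fixed before the data were examined. A nucleus was kept with at least 300 genes and at most 10% of UMIs from mitochondrially encoded genes, which left 104350. Doublet scores were computed with Scrublet as built into scanpy 1.11.5, and in each library the nuclei with the highest scores, 0.8% for every 1000 barcodes, were marked as doublets (10264) and left out. That leaves 94086 nuclei for every count and share. All 104350, the marked ones included, were clustered on 3000 variable genes and 40 principal components, without any integration between libraries. The clustering used 20 neighbours and Leiden resolution 1 (igraph 0.11.9). This gave 26 clusters, numbered from 0 and not in order of size. Clusters were named from fixed markers of 17 cell types. The thresholds of that naming were set after the clusters had been seen: a marker score of at least 0.65, at least 3 markers each found in 10% of nuclei, and no name where a second type scored at least 0.6 within 0.2 of the first. Erythroid and cycling markers were scored but left out of this rule. Cluster 8, named endothelial at 0.888, scored 1.0 for erythroid markers. Endothelial and lymphatic endothelial, pericyte and smooth muscle, and macrophage and dendritic types did not count as second types to each other. Named classes are 12, with 91878 nuclei. The 2208 unnamed nuclei lie in 2 clusters with adipocyte and endothelial markers together (clusters 7 and 15) and in 2 with few markers (clusters 17 and 25). Cluster 7 holds 1.06 ± 0.326, 2.06 ± 1.12 and 2.60 ± 1.80% of kept nuclei in ND, HFD and DHM_HFD (SD, n = 3), and cluster 15 holds 0.0520 ± 0.0113, 0.0843 ± 0.126 and 0.101 ± 0.0471%. Cluster 17 holds 0.0460 ± 0.0493, 0.0577 ± 0.0415 and 0.0953 ± 0.0882%, and cluster 25 holds 0.0817 ± 0.0247, 0.0817 ± 0.0293 and 0.0250 ± 0.0197%.

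For each class with at least 20 nuclei in every library (8 classes), raw counts were summed per library and gene, since nuclei of one library are not replicates. Genes were filtered with filterByExpr and libraries scaled by TMM. The 3 groups were fitted together without covariates, and groups compared with the quasi-likelihood test of edgeR 4.0.16 under R 4.3.3. Adjusted p-values are from the method of Benjamini and Hochberg, within class and comparison, with 0.05 as the threshold. Changes are given as log2 fold change ± standard error. Levels are CPM, counts scaled to the same library total by edgeR, as mean ± SD over 3 libraries. Of the 31 gene lists fixed before the data were examined, each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists. An estimated correlation and the self-contained test fry stand beside it. Shares of nuclei per library were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.10, adjusted over 36 tests. The share of nuclei with a Ucp1 UMI was taken after each nucleus was thinned to 1000 UMIs, and nuclei below that were left out.

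Genes are named by a rule written before the data were examined. In adipocyte nuclei it takes, per comparison, the 8 largest rises and the 8 largest falls among genes past the threshold with at least 10 CPM in a group and no overlap between the groups, leaving out predicted genes. It adds 16 fixed genes whatever their result, and up to 4 members per list by smallest p. In the other classes it takes 3 rises and 3 falls. For opposite changes it takes 6 of each kind by the product of both changes. Genes outside this rule are marked in the text, and a few that the rule takes are not reported here.

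The tests were tested on simulated data. Counts were drawn from the mean, depth and dispersion of the adipocyte libraries without a group difference, and 200 genes per comparison were changed 1.5-fold, 2-fold or 4-fold. For HFD against ND, 14.9, 50.7 and 86.4% were recovered, with 3 false calls of 104. For DHM_HFD against HFD, 28.4, 63.6 and 92.5% were recovered, with 10 false calls of 133. A smaller change is therefore often missed. The overlap of opposite changes was set against 50 simulations of unchanged groups that share the HFD libraries.

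The alternatives tried were RLE size factors, DESeq2 1.42.0, no filter on low counts, the 2 groups of a comparison alone, doublets kept, a stricter nucleus filter (500 genes, 5%), leaving out genes over 5 times higher in another class, the replicate number as a block, and each library left out in turn. For lists there were also the 2 other tests. For shares there were finer clusters (resolution 2), another denominator and an edgeR test on nuclei, and for Ucp1 2000 UMIs or no thinning. Another 2 alternatives were chosen after seeing the data: without the 2 libraries of most barcodes, and without 3 adipocyte clusters that come mostly from 1 library or are led by stress or interferon genes. The closing section gives their effect. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Sex-linked genes, cell communication, transcription factor networks and integration across samples were not analysed here.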

Results

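Single-nucleus RNA-seq counts of mouse brown adipose tissue were available for 9 libraries, 3 each from mice on a normal diet (ND), on a high-fat diet (HFD) and on the high-fat diet with dihydromyricetin, a plant flavonoid (DHM_HFD). The comparisons ask what the high-fat diet changed (HFD against ND), what the compound changed on it (DHM_HFD against HFD), and what remained different from the normal diet (DHM_HFD against ND). ND libraries held 54385988, 52194951 and 48349519 UMIs in 11216, 11097 and 11299 barcodes. HFD libraries held 48705252, 50812607 and 48145995 in 15402, 9622 and 8981, and DHM_HFD libraries 49197255, 47959889 and 54401107 in 9339, 9652 and 17773. After filters and removal of doublets, 94086 nuclei were kept.

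The kept nuclei fell into 12 named classes. Adipocytes were the largest, with 63.1 ± 1.53% of kept nuclei in ND, 60.5 ± 4.23% in HFD and 58.5 ± 3.20% in DHM_HFD (SD, n = 3). Endothelial cells came next with 23.1 ± 1.56, 25.2 ± 3.32 and 26.8 ± 5.17%. Adipocyte nuclei of ND lay mostly in another cluster than those of HFD and DHM_HFD. In ND, cluster 0 held 78.8 ± 10.1% of adipocyte nuclei. In HFD, cluster 4 held 66.6 ± 9.21% and cluster 1 held 18.1 ± 11.1%. In DHM_HFD, clusters 3, 4 and 1 held 38.4 ± 9.59, 33.4 ± 4.28 and 16.9 ± 13.3%. Cluster 3 held only 4.84 ± 2.73% in HFD and 4.75 ± 3.85% in ND, so HFD and DHM_HFD shared clusters 4 and 1 in part. Cluster 1 was largest in the 2 most loaded libraries, with 30.9, 11.1 and 12.4% in HFD replicates 1 to 3 and 5.69, 13.5 and 31.6% in DHM_HFD replicates 1 to 3. Expression was therefore compared in adipocyte nuclei first, with all adipocyte clusters of a library pooled.

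In adipocyte nuclei many genes differed between HFD and ND. Ryr2, which encodes a calcium release channel, rose from 16.8 ± 5.66 CPM in ND to 323 ± 34.6 CPM in HFD (log2 change 4.27 ± 0.21, adjusted p = 1.31e-06). Eya2, a transcriptional coactivator gene, rose from 1.17 ± 0.225 to 20.1 ± 2.41 CPM (4.10 ± 0.22, adjusted p = 1.46e-06). Other large rises were in Gfra1, a receptor gene for glial cell line-derived neurotrophic factor (3.42 ± 0.41), Cacna2d3, a calcium channel subunit gene (3.27 ± 0.36), and Shisa6 (3.24 ± 0.20). Ddit4, a stress-induced inhibitor of mTORC1, stood at 26.6 ± 7.2 against 3.02 ± 1.67 CPM (3.14 ± 0.35). The immediate early gene Fosb stood at 13.6 ± 13.4 against 0.464 ± 0.253 CPM (4.84 ± 1.23). The largest falls were in Prune2 (-4.64 ± 0.90; 4.08 ± 1.46 against 100.9 ± 137 CPM), Tmem132b (-4.52 ± 0.53), Hephl1 (-4.36 ± 0.92) and Srrm3 (-4.13 ± 0.56). Cib4, which encodes a calcium-binding protein, fell from 30.7 ± 5.24 to 2.27 ± 0.340 CPM (-3.75 ± 0.20). Rassf2 (-3.08 ± 0.42), Avil (-2.92 ± 0.30) and Iqck (-2.82 ± 0.19) fell too. On GRCm38, Ryr2 (ENSMUSG00000021313) lies on chromosome 13 at 11553102 to 12106945 and Eya2 (ENSMUSG00000017897) on chromosome 2 at 165595032 to 165771727. Cib4 (ENSMUSG00000053194) lies on chromosome 5 at 30485583 to 30545836.

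In all, 4588 of 20211 genes tested with edgeR changed between HFD and ND, 2441 higher and 2147 lower. For 42.1% of tested genes the 3 libraries of one group all lay above the 3 of the other, where chance gives 10%. The count was 2961 without ND replicate 1, 2710 without HFD replicate 2, 2902 without HFD replicate 3 and 2859 without the 2 most loaded libraries. Of the 56 called genes named for this comparison, 53 kept their call with any single library left out. Fosb lost it without ND replicate 1 or 2 or HFD replicate 1, and Acly and Nr4a1 as described with their groups.

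**Figure D1:**
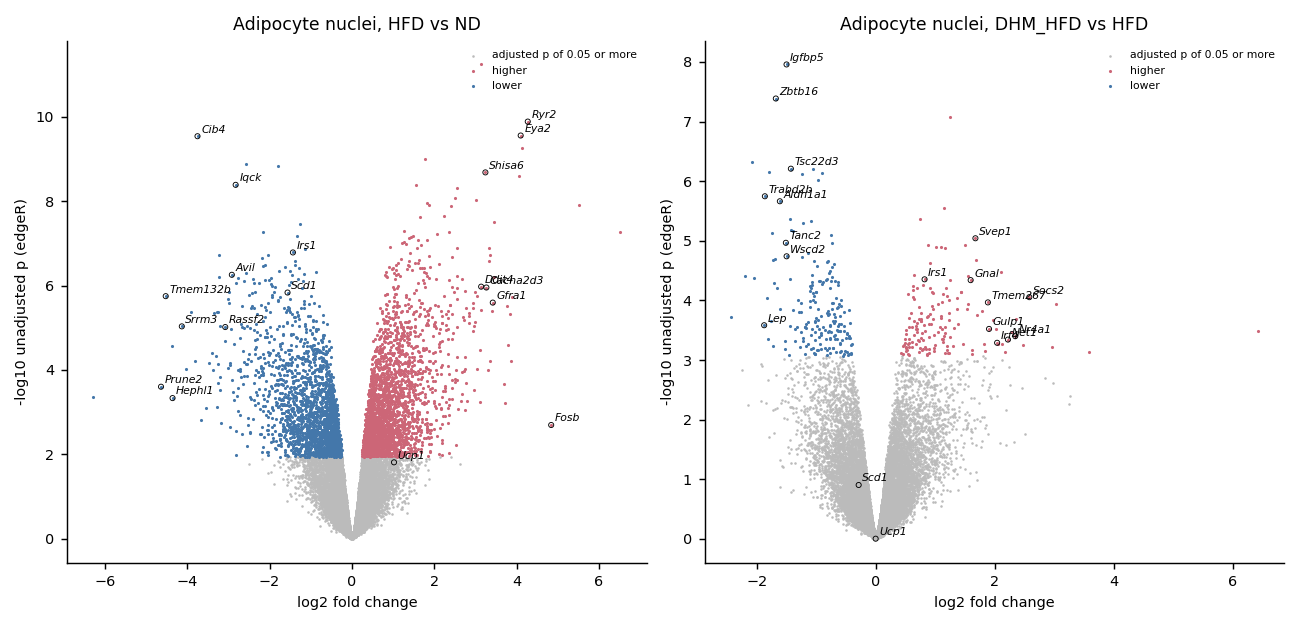
Log2 fold change (horizontal) against -log10 of the unadjusted edgeR p (vertical) for 20211 genes in adipocyte nuclei, HFD against ND on the left and DHM_HFD against HFD on the right. Each point is a gene, red higher and blue lower past an adjusted p of 0.05 (4588 and 350 genes), and circled genes are named in the text.

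Genes of fat synthesis from glucose were lower in HFD. Of 17 measured members of the de novo lipogenesis list, 9 fell, 1 rose and 7 did not pass the test, and 11 fell and 1 rose adjusted over the list alone. Scd1, the stearoyl-CoA desaturase gene (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), fell from 4623 ± 544 to 1563 ± 127 CPM (-1.56 ± 0.18, adjusted p = 2.09e-04). Elovl5, a fatty acid elongase gene, fell from 107 ± 39.8 to 27.8 ± 0.834 CPM (-1.95 ± 0.22). Me1, the cytosolic malic enzyme gene, fell from 375 ± 267 to 116 ± 2.02 CPM (-1.70 ± 0.35). Srebf1, which encodes a transcription factor of lipogenic genes, fell from 100.1 ± 22.5 to 63.2 ± 0.435 CPM (-0.66 ± 0.14). Acly, the ATP citrate lyase gene, fell from 591 ± 426 to 239.8 ± 85.1 CPM (-1.30 ± 0.41, adjusted p = 0.0410). Fasn, the fatty acid synthase gene, stood at 493 ± 167 against 729 ± 183 CPM (-0.57 ± 0.22, adjusted p = 0.0899). The list as a whole was lower by camera (adjusted p = 0.00463; adjusted p = 0.755 with an estimated correlation). ND replicate 3 stands apart here: 97.3% of the nuclei of cluster 2, led by Prune2, Acly, Hephl1, Scd2 and Me1, came from it. Without this cluster and 2 others led by stress or interferon genes (an alternative chosen after seeing the data), Prune2 stood at -2.95, Me1 at -1.12 and Scd1 at -1.41, all past the threshold, whereas Acly stood at -0.49 (adjusted p = 0.154). Acly also lost its call without ND replicate 3, HFD replicate 2, HFD replicate 3 or DHM_HFD replicate 3.

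Sterol synthesis was lower as well, with 9 of 18 members down, none up and 9 not past the test (10 down adjusted over the list alone). Among them was Idi1, a gene of cholesterol synthesis (-1.15 ± 0.22; 4.07 ± 0.0112 against 9.05 ± 2.38 CPM). The camera adjusted p was 0.00226 (adjusted p = 0.755 with an estimated correlation). Ribosomal protein genes followed, with 6 of 24 down, none up and 18 not past the test (9 down adjusted over the list alone). Rps24 (-0.63 ± 0.13) and Rpl4 (-0.47 ± 0.09) are examples, and the camera adjusted p was 0.00148 (adjusted p = 0.755 with an estimated correlation).

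Genes of fat storage and fat burning were higher in HFD. In the list of triglyceride synthesis and lipid droplets, 7 of 18 members rose, none fell and 11 did not pass the test (9 up adjusted over the list alone). Gpd1, the glycerol-3-phosphate dehydrogenase gene, rose from 966 ± 120 to 1671 ± 48.1 CPM (0.79 ± 0.14, adjusted p = 0.00204). The droplet coat gene Plin5 rose from 138 ± 16.4 to 203 ± 10.5 CPM (0.56 ± 0.12), and Lpin2 by 0.46 ± 0.09. In fatty acid oxidation, 7 of 21 rose, none fell and 14 did not pass (9 up adjusted over the list alone). Hadha stood at 993 ± 35.2 against 699 ± 89.6 CPM (0.51 ± 0.11) and Cpt1a, the carnitine palmitoyltransferase gene of liver type, at 5.16 ± 0.951 against 2.65 ± 0.325 CPM (0.96 ± 0.20). In glucose uptake and glycolysis, 6 of 19 rose, 1 fell and 12 did not pass (6 and 1 adjusted over the list alone). The phosphofructokinase gene Pfkl rose by 0.92 ± 0.13 and the hexokinase gene Hk1 by 0.86 ± 0.12. The 3 lists were higher by camera with adjusted p = 0.00255, 0.00779 and 0.0272 in this order (adjusted p = 0.755 with an estimated correlation for each).

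The lists of hypoxia response, circadian clock, and immediate early and heat shock genes were higher too. For hypoxia response, 6 of 15 rose, 1 fell and 8 did not pass (6 and 1 adjusted over the list alone). Egln1, an oxygen-sensing prolyl hydroxylase gene, rose from 122 ± 13.3 to 292 ± 2.82 CPM (1.26 ± 0.11, adjusted p = 5.48e-05). P4ha1, a collagen prolyl hydroxylase gene, rose from 75.0 ± 23.2 to 238 ± 55.0 CPM (1.67 ± 0.21). For the clock, 10 of 19 rose, 2 fell and 7 did not pass (10 and 2 adjusted over the list alone). Nr1d1, which encodes the repressor REV-ERB alpha, rose from 12.9 ± 2.80 to 41.0 ± 7.19 CPM (1.67 ± 0.20). Per1 rose from 32.5 ± 0.243 to 59.1 ± 4.29 CPM (0.86 ± 0.10), while Cry1 fell from 45.5 ± 6.69 to 17.3 ± 1.68 CPM (-1.39 ± 0.14). Among immediate early and heat shock genes, 5 of 20 rose, 1 fell and 14 did not pass (6 and 1 adjusted over the list alone), such as Hsph1 (1.47 ± 0.24) and Ier3 (1.51 ± 0.25). Cluster 14, with Fosb, Fos, Atf3 and Hspa1b among its leading genes, held 0.01 ± 0.01% of kept nuclei in ND, 0.839 ± 0.231% in HFD and 0.561 ± 0.669% in DHM_HFD. The last mean rests on DHM_HFD replicate 3, with 0.278, 0.079 and 1.325% in replicates 1 to 3. Camera gave adjusted p = 0.0102, 0.00916 and 0.00916 for the 3 lists (adjusted p = 0.608, 0.608 and 0.755 with an estimated correlation). By fry, only hypoxia response and the clock passed, each with adjusted p = 0.00356.

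In all, 9 of 31 lists passed camera between HFD and ND, and the other 22 did not. Of the 10 splits of these 6 libraries, 3, the real one included, gave at least 9 lists, with 12 in another, so this count is not above what regrouping gives. In insulin signalling, 4 of 20 members rose, 5 fell and 11 did not pass (5 and 6 adjusted over the list alone; camera adjusted p = 0.889, and adjusted p = 0.922 with an estimated correlation). The insulin receptor substrate gene Irs1 (ENSMUSG00000055980, chromosome 1, 82233101 to 82291416) fell from 295 ± 21.9 to 109 ± 6.73 CPM (-1.43 ± 0.13, adjusted p = 7.51e-05). Tbc1d4, whose product regulates glucose transporter traffic, fell from 584 ± 56.5 to 360 ± 36.7 CPM (-0.70 ± 0.11), and Foxo1 rose from 569 ± 34.4 to 934 ± 30.3 CPM (0.72 ± 0.13). In the thermogenic program, 5 of 22 rose, 1 fell and 16 did not pass (6 and 2 adjusted over the list alone; camera adjusted p = 0.102). Pank1, a pantothenate kinase gene, stood at 1660.1 ± 123.4 against 1034 ± 55.3 CPM (0.68 ± 0.11). Ebf2, a transcription factor gene of brown fat, fell (-0.61 ± 0.15), a call that ended without the 2 most loaded libraries. Lipolysis and lipid uptake had 5 of 18 up, 1 down and 12 not past the test (camera adjusted p = 0.584). Lipe, the hormone-sensitive lipase gene, stood at 1131 ± 27.5 against 760 ± 65.2 CPM (0.57 ± 0.11), and Lipa (1.09 ± 0.12) and Gpihbp1 (1.28 ± 0.17) rose. The unfolded protein response had 6 of 19 up, 2 down and 11 not past the test (camera adjusted p = 0.352), with the chaperone gene Hspa5 at 0.74 ± 0.12. No gene of nuclear-encoded oxidative phosphorylation passed among 27 (camera adjusted p = 0.688).

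**Figure D2:**
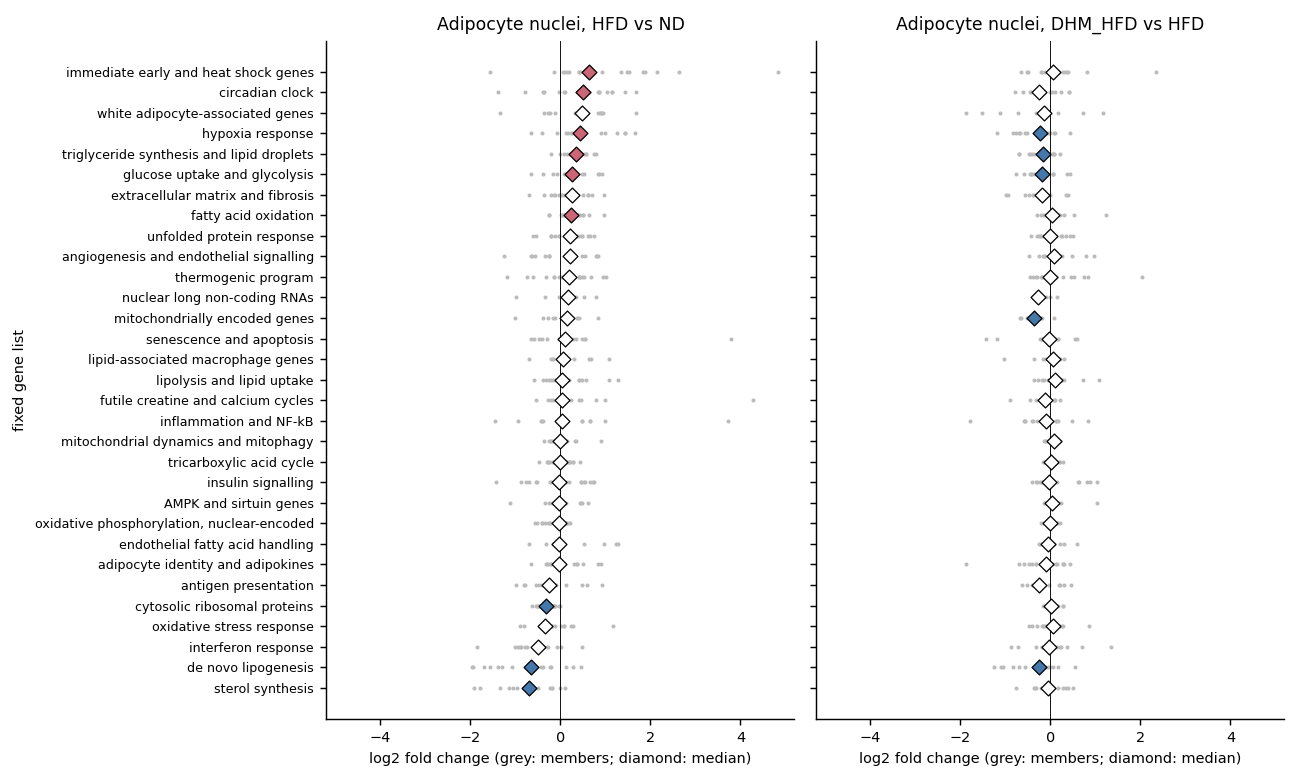
Log2 fold changes of the members (grey points) and their median (diamonds) for 31 fixed gene lists in adipocyte nuclei, HFD against ND on the left and DHM_HFD against HFD on the right. Filled diamonds, red higher and blue lower, mark lists past an adjusted camera p of 0.05, which are 9 on the left and 5 on the right.

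Among the fixed genes of brown and white fat, most did not pass the test between HFD and ND. Ucp1, the uncoupling protein gene (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), stood at 1186 ± 389 CPM in HFD against 584 ± 331 in ND (1.02 ± 0.36, adjusted p = 0.0612). Log2 changes were -1.18 ± 0.43 for the transcription factor gene Irf4 (adjusted p = 0.0659), 0.83 ± 0.35 for the leptin gene Lep (0.112), -0.22 ± 0.10 for the adiponectin gene Adipoq (0.138) and -0.33 ± 0.25 for Ppargc1a (0.368). For the rest they were 0.22 ± 0.15 for Prdm16 (adjusted p = 0.328), -0.07 ± 0.13 for Pparg (0.737), -0.14 ± 0.31 for Dio2 (0.784), -0.74 ± 0.44 for Elovl3 (0.249), 0.05 ± 0.13 for Pnpla2 (0.806), -0.16 ± 0.11 for Cd36 (0.291) and 0.31 ± 0.19 for Pck1 (0.272). Some of these passed under alternatives. Without the filter Irf4, Lep, Ucp1, Fasn and Elovl3 passed. Irf4 also passed with the 2 groups alone and without ND replicate 1 or DHM_HFD replicate 1 or 2. Lep passed without ND replicate 3 and without the 3 adipocyte clusters, Ucp1 and Pck1 without ND replicate 2, and Adipoq without ND replicate 1. Fasn passed by DESeq2, without HFD replicate 1 and without the 2 most loaded libraries.

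The share of adipocyte nuclei with a Ucp1 UMI, at 1000 UMIs per nucleus, was 37.4 ± 15.0% in ND, 61.0 ± 9.07% in HFD and 59.9 ± 11.7% in DHM_HFD (SD, n = 3). The 3 libraries of HFD all lay above those of ND by a narrow margin, the lowest at 54.1% and the highest of ND at 53.2% (difference 23.6 points, exact p = 0.100, the smallest possible). With doublets kept the groups overlapped (24.0 points, exact p = 0.2). DHM_HFD differed from ND by 22.6 points (exact p = 0.2) and from HFD by -1.08 points (exact p = 0.9). Endothelial nuclei, taken as the background of free RNA, had a Ucp1 UMI in 9.87 ± 3.89, 24.4 ± 2.80 and 21.5 ± 7.25% of nuclei, with a median depth of 1833 UMIs against 4950.5 in adipocytes. Without thinning, the adipocyte shares were 76.3, 92.0 and 89.6%, and the difference between HFD and ND was 15.7 points (exact p = 0.2).

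**Figure D3:**
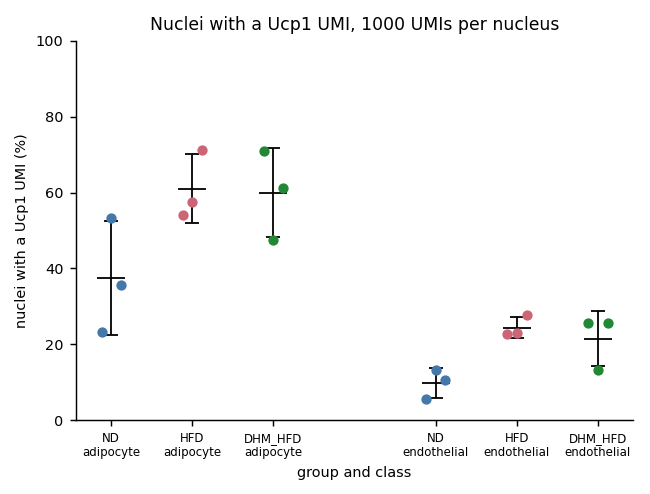
Share of nuclei with a Ucp1 UMI (%) after thinning to 1000 UMIs per nucleus, in adipocyte and endothelial nuclei of the 3 groups. Points are libraries, and bars are the mean and SD of 3; in adipocytes the means are 37.4, 61.0 and 59.9%.

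With dihydromyricetin added to the high-fat diet, a smaller set of adipocyte genes differed from HFD. Zbtb16, a transcription factor gene known to be induced by glucocorticoids (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222), fell from 2086 ± 258 to 651 ± 109 CPM (-1.68 ± 0.14, adjusted p = 4.15e-04). Igfbp5, which encodes a binding protein of insulin-like growth factors, fell from 28.5 ± 0.676 to 10.1 ± 0.936 CPM (-1.50 ± 0.11, adjusted p = 2.22e-04). Tsc22d3, another gene known to be induced by glucocorticoids, fell from 348 ± 92.6 to 129 ± 4.40 CPM (-1.43 ± 0.15, adjusted p = 0.00171), and Lep from 25.4 ± 3.08 to 6.92 ± 0.726 CPM (-1.88 ± 0.37, adjusted p = 0.0299). Other falls were in Trabd2b (-1.86 ± 0.22), the retinaldehyde dehydrogenase gene Aldh1a1 (-1.61 ± 0.19), Tanc2 (-1.51 ± 0.21) and Wscd2 (-1.50 ± 0.22). Svep1, an extracellular matrix gene, rose from 329.6 ± 68.5 to 1053 ± 215 CPM (1.68 ± 0.23, adjusted p = 0.00834). Socs2, an inhibitor gene of cytokine signalling, rose from 4.45 ± 0.696 to 26.7 ± 18.1 CPM (2.58 ± 0.45, adjusted p = 0.0194). The nuclear receptor gene Nr4a1 rose from 25.8 ± 9.73 to 131 ± 68.4 CPM (2.35 ± 0.48, adjusted p = 0.0347) and Irf4 from 18.9 ± 3.82 to 77.6 ± 39.3 CPM (2.04 ± 0.43, adjusted p = 0.0395). Net1 (2.22 ± 0.47), Gulp1 (1.90 ± 0.38), Tmem267 (1.88 ± 0.33) and Gnal (1.60 ± 0.26) rose too.

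Of 20 insulin signalling genes, 3 rose, none fell and 17 did not pass (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.742; median -0.04 and mean 0.11, so the 2 differ in sign). Irs1 rose from 109 ± 6.73 to 193 ± 39.4 CPM (0.82 ± 0.13, adjusted p = 0.0156), Tbc1d4 from 360 ± 36.7 to 553 ± 23.7 CPM (0.62 ± 0.11, adjusted p = 0.0194) and the kinase gene Akt1 from 11.6 ± 0.461 to 18.0 ± 0.529 CPM (0.64 ± 0.11, adjusted p = 0.0196). Camera called 5 lists lower in DHM_HFD than HFD, though few of their members passed alone. Of the 10 splits of these libraries, 2, the real one included, gave at least 5 lists, with 8 in the other. In hypoxia response, 1 of 15 fell, Egln1 at -0.68 ± 0.11, and 14 did not pass (6 down adjusted over the list alone; camera adjusted p = 0.0163). Of mitochondrially encoded genes, 0 of 13 passed (1 down adjusted over the list alone; camera adjusted p = 0.0163), and of triglyceride synthesis and lipid droplets 0 of 18 (4 down adjusted over the list alone; camera adjusted p = 0.0330). De novo lipogenesis had 1 of 17 down and 16 not past the test (4 down adjusted over the list alone; camera adjusted p = 0.0372). This was Pnpla3 with 139.8 ± 7.97 against 299.6 ± 19.7 CPM (-1.10 ± 0.18). Glucose uptake and glycolysis had 1 of 19 down, the pyruvate kinase gene Pkm at -0.43 ± 0.08, and 18 not past the test (5 down adjusted over the list alone; camera adjusted p = 0.0372). With an estimated correlation none held (adjusted p = 0.762 for each), and none passed by fry. The list count was 2 without HFD replicate 1, DHM_HFD replicate 1 or DHM_HFD replicate 2, 3 without HFD replicate 3, and 1 (hypoxia response) without the 2 most loaded libraries. Further members that passed were Ebf1 (-0.59 ± 0.11), an adipocyte transcription factor gene, Camkk2 (1.05 ± 0.19) and Nrp1 (0.79 ± 0.13).

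The fixed genes of brown and white fat did not pass between DHM_HFD and HFD apart from Irf4 and Lep. Ucp1 stood at 1184 ± 355 against 1186 ± 389 CPM (log2 change -0.00 ± 0.36, adjusted p = 0.999). Log2 changes of the other genes of brown fat were 0.13 ± 0.25 for Ppargc1a, -0.22 ± 0.15 for Prdm16, 0.74 ± 0.31 for Dio2 and 0.84 ± 0.44 for Elovl3, and Pparg stood at -0.10 ± 0.13 and Adipoq at 0.12 ± 0.10. Among genes of lipid metabolism, Fasn stood at -0.84 ± 0.23 (adjusted p = 0.0857), Acly at -1.26 ± 0.42 (adjusted p = 0.154), Scd1 at -0.29 ± 0.17, Lipe at -0.27 ± 0.11, Pnpla2 at 0.11 ± 0.13, Cd36 at 0.22 ± 0.11 and Pck1 at 0.08 ± 0.19. Fasn and Acly passed without the filter, without ND replicate 3 and without the 3 adipocyte clusters, Fasn also by DESeq2 and Acly with the 2 groups alone. Dio2 and Elovl3 passed without the filter.

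In all, 350 adipocyte genes changed between DHM_HFD and HFD, 156 higher and 194 lower, and 22.9% of tested genes did not overlap between the groups (10% by chance). This count depends on single libraries: it was 55 without HFD replicate 1, 46 without HFD replicate 2, 120 without HFD replicate 3, 158 without DHM_HFD replicate 2 and 120 without DHM_HFD replicate 3. It was 14 without the 2 most loaded libraries, against 951 by DESeq2 and 1374 without a filter on low counts. Of the 31 called genes named for this comparison, 21 lost their call without HFD replicate 1, 21 without HFD replicate 2, and 16 without HFD replicate 3. Without DHM_HFD replicates 1, 2 and 3 this number was 6, 11 and 14, and it was 2 each without ND replicates 1 and 2. Zbtb16, Tsc22d3, Igfbp5, Svep1, Trabd2b, Aldh1a1, Tanc2, Mettl24 and Eya2 kept it with any single library left out.

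Many adipocyte genes changed in opposite directions in the 2 comparisons. Zbtb16 rose from 568 ± 32.4 CPM in ND to 2086 ± 258 in HFD (1.88 ± 0.14) and stood at 651 ± 109 in DHM_HFD, where it did not differ from ND by the test (0.20 ± 0.13, adjusted p = 0.350). Igfbp5 went from 3.25 ± 0.134 to 28.5 ± 0.676 and 10.1 ± 0.936 CPM (3.13 ± 0.12 and -1.50 ± 0.11), and Eya2 from 1.17 ± 0.225 to 20.1 ± 2.41 and 7.67 ± 1.95 CPM (4.10 ± 0.22 and -1.39 ± 0.18). Wscd2 went from 1.99 to 11.6 and 4.10 CPM (2.55 ± 0.23 and -1.50 ± 0.22) and Tanc2 from 14.1 to 43.4 and 15.2 CPM (1.63 ± 0.21 and -1.51 ± 0.21). Timp3, a tissue inhibitor of metalloproteinases, went from 49.3 ± 13.7 to 174 ± 62.4 and 81.8 ± 13.9 CPM (1.82 ± 0.24 and -1.09 ± 0.24). In the other direction, Mettl24 (ENSMUSG00000045555, chromosome 10, 40683282 to 40811083) went from 154 ± 9.96 to 44.2 ± 5.67 and 105 ± 6.69 CPM (-1.80 ± 0.11, adjusted p = 3.73e-06, and 1.24 ± 0.11, adjusted p = 5.63e-04). Nr4a1 went from 76.1 ± 38.8 to 25.8 ± 9.73 and 131 ± 68.4 CPM (-1.56 ± 0.47 and 2.35 ± 0.48). Tmem267 changed by -1.54 ± 0.33 and 1.88 ± 0.33, Srgap3 by -1.90 ± 0.28 and 1.53 ± 0.28, Fmo4, a flavin monooxygenase gene, by -1.97 ± 0.21 and 1.04 ± 0.21, and Cib4 by -3.75 ± 0.20 and 0.90 ± 0.20. Nr4a1 lost its fall in HFD without ND replicate 2, ND replicate 3, HFD replicate 2 or HFD replicate 3.

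In all, 148 genes rose in HFD and fell in DHM_HFD, and 87 fell and then rose, 235 together, where independent lists would share 23.4 and 16.6. Only 4 genes rose in both comparisons and 3 fell in both (18.8 and 20.6 for independent lists). Both comparisons use the HFD libraries, which alone pull the changes apart. In 50 simulations of unchanged groups sharing them, the correlation of log2 changes was -0.505 (real value -0.508), with at most 1 gene called in opposite directions. With no group difference drawn, few genes can be called in either comparison, so that number is no measure for the 235. Groups with a change by diet and none by the compound were not simulated. The covariance was -0.137 in the data against -0.0365 ± 0.00103 in the simulations, a difference of -0.100. The HFD libraries cannot be split into parts of at least 2, so part of the excess may come from the shared libraries. The count was 44 without HFD replicate 1, 38 without HFD replicate 2, 89 without HFD replicate 3, 117 without DHM_HFD replicate 2, 79 without DHM_HFD replicate 3 and 12 without the 2 most loaded libraries.

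**Figure D4:**
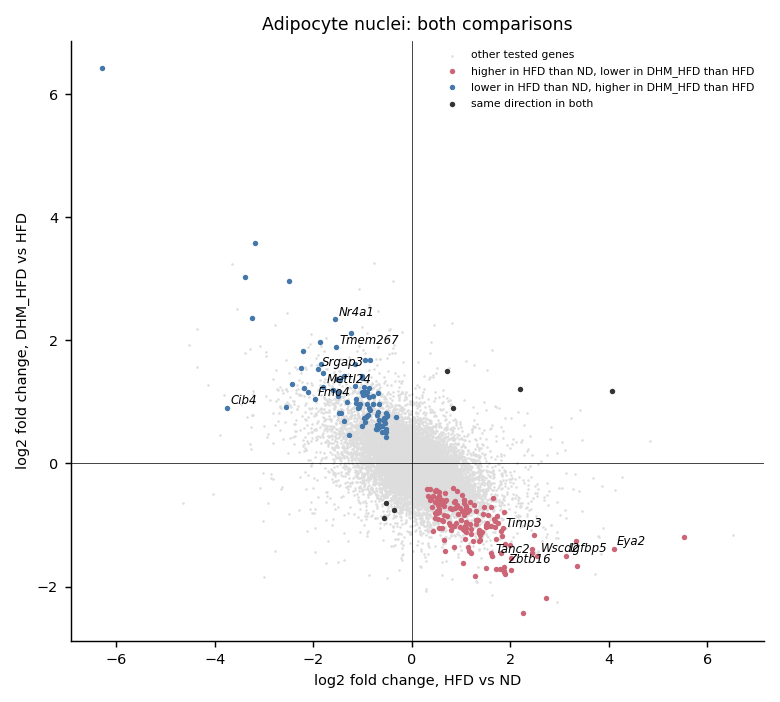
Log2 fold change of 20211 adipocyte genes, HFD against ND (horizontal) and DHM_HFD against HFD (vertical). Each point is a gene; 148 (red) rose and then fell, 87 (blue) fell and then rose, and 7 (dark) changed the same way in both, with the 12 named genes marked.

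Adipocyte nuclei of DHM_HFD also differed from those of ND. Ryr2 stood at 276 ± 10.5 against 16.8 ± 5.66 CPM (4.04 ± 0.21, adjusted p = 1.61e-06), Gfra1 at 40.8 ± 17.2 against 2.06 ± 1.35 CPM (4.29 ± 0.42), and Shisa6 at 46.3 ± 12.8 against 2.93 ± 0.597 CPM (3.98 ± 0.21). The potassium channel gene Kcnc2 rose by 3.41 ± 0.30, Ankrd33b by 2.99 ± 0.27, Cacna2d3 by 2.85 ± 0.36, the amino acid transporter gene Slc7a8 by 2.61 ± 0.17 and Fosb by 5.21 ± 1.23. In the de novo lipogenesis list 12 of 17 members fell, 1 rose and 4 did not pass (13 and 1 adjusted over the list alone; camera adjusted p = 2.95e-06, adjusted p = 0.715 with an estimated correlation). Acly stood at 100.01 ± 26.7 against 591 ± 426 CPM (-2.56 ± 0.43, adjusted p = 0.00315) and Scd1 at 1281 ± 359 against 4623 ± 544 CPM (-1.85 ± 0.18, adjusted p = 1.35e-04). Fasn stood at 276 ± 35.7 against 729 ± 183 CPM (-1.40 ± 0.23, adjusted p = 0.00258), and Scd2 changed by -3.0 ± 0.60. Falls were also seen in Prune2 (-5.28 ± 0.94), Rassf2 (-3.48 ± 0.43), the sortilin family gene Sorcs2 (-3.40 ± 0.38), Als2cl (-3.05 ± 0.31), Srrm3 (-2.86 ± 0.51), Cib4 (-2.85 ± 0.19) and Tmem132b (-2.60 ± 0.47). Without cluster 2 of ND replicate 3 and the 2 other clusters, Prune2 stood at -3.56, Sorcs2 at -2.93, Scd2 at -2.23, Acly at -1.77, Scd1 at -1.70 and Fasn at -1.07, all past the threshold. Irs1 fell too (-0.61 ± 0.13, a call that ended without the 2 most loaded libraries). Fosb lost its call without ND replicate 1, ND replicate 2 or DHM_HFD replicate 3. Other fixed genes did not pass, such as Ucp1 (1.02 ± 0.36, adjusted p = 0.0790) and Lep (-1.05 ± 0.37, adjusted p = 0.0734). The rest were Lipe (0.30 ± 0.11), Irf4 (0.86 ± 0.42), Dio2 (0.60 ± 0.31), Pck1 (0.38 ± 0.19), Pnpla2 (0.16 ± 0.13), Elovl3 (0.10 ± 0.43), Cd36 (0.05 ± 0.11), Prdm16 (0.00 ± 0.15), Adipoq (-0.09 ± 0.10), Pparg (-0.17 ± 0.13) and Ppargc1a (-0.20 ± 0.25). Of these, Ucp1, Lep, Irf4 and Pck1 passed without the filter or without ND replicate 2, Dio2 without the filter, and Lipe by DESeq2 or without DHM_HFD replicate 2.

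In all, 2986 adipocyte genes changed between DHM_HFD and ND, 1577 higher and 1409 lower (31.5% of tested genes without overlap, 10% by chance). The count was 1567 without ND replicate 1, 1627 without DHM_HFD replicate 3, 2057 with the 2 groups fitted alone and 1397 without the 2 most loaded libraries.

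Other cell types changed with the high-fat diet as well. In endothelial cells 1085 of 14796 genes rose and 667 fell. At the finer resolution, endothelial nuclei also lay partly in different clusters by group. Finer cluster 8 held 0.069, 0.188 and 0.019% of kept nuclei in ND, 4.11, 12.6 and 10.2% in HFD and 3.98, 1.88 and 1.48% in DHM_HFD. Finer cluster 6 held 11.1, 10.3 and 8.05% in ND, 3.46, 2.79 and 1.93% in HFD and 6.68, 12.3 and 4.21% in DHM_HFD. Counts do not rank the classes, since in the simulated data 34.3% of changes of 1.5-fold were recovered in endothelial cells, 9% in progenitors, 6% in pericytes and 0% in macrophages. Genes with higher levels in adipocyte nuclei made up 37.3% of the changed genes in endothelial cells (46.4% of those tested), 30.5% in progenitors (45.4%), 23.7% in pericytes (47.5%) and 30.4% in macrophages (44.9%). Some of them are marked below. Immediate early and heat shock genes were higher in 5 of these other classes, with none down. In endothelial nuclei 13 of 19 rose (6 not past the test; camera adjusted p = 2.54e-07, adjusted p = 0.396 with an estimated correlation). In adipocyte progenitors 14 of 19 rose (5 not past; 3.13e-16, and adjusted p = 0.265 with an estimated correlation) and in pericytes 10 of 19 (9 not past; 2.05e-13, and adjusted p = 0.210 with an estimated correlation). In Schwann cells 5 of 12 rose (7 not past; 1.45e-11, and adjusted p = 0.178 with an estimated correlation). In macrophages only 1 of 19 rose (18 not past; 2.84e-08, and adjusted p = 0.458 with an estimated correlation). Smooth muscle had 0 of 8 past the test and the list did not pass (camera adjusted p = 0.105), and in lymphocytes the list was not tested. A finer endothelial cluster with Egr1 and Fos among its leading genes held 6.87, 0.541 and 0.636% of kept nuclei in HFD replicates 1 to 3. It held 0.735, 1.286 and 1.694% in ND and 0.637, 1.135 and 8.17% in DHM_HFD, so it follows the most loaded libraries. An effect of sample handling on these genes was not tested and cannot be told apart from one of diet. Fosb was at 24.7 ± 16.3 against 1.56 ± 1.89 CPM in endothelial nuclei (3.87 ± 0.83), at 208 ± 91.8 against 0.932 ± 1.20 in progenitors (7.62 ± 0.93) and at 87.9 ± 40.1 against 0.706 ± 0.611 in pericytes (6.64 ± 0.98). The ND libraries held 1441802 to 1987155 UMIs in progenitors and 742940 to 967608 in pericytes. Levels of Fosb in ND thus rest on a few UMIs in these 2 classes, and the size of both folds is uncertain. In Schwann cells it was found in HFD at 429 ± 238 CPM with no count in ND (at least 42.3-fold over the group, with a floor of 3 counts). Endothelial nuclei also had higher hypoxia response genes (8 of 15 up, 7 not past; camera adjusted p = 1.21e-05, adjusted p = 0.396 with an estimated correlation) and clock genes (7 of 19 up, 12 not past; 0.00144, and adjusted p = 0.436 with an estimated correlation).

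In endothelial nuclei, Ica1l rose from 9.04 ± 4.61 to 62.5 ± 12.6 CPM with the high-fat diet (2.81 ± 0.31, adjusted p = 2.37e-04) and fell to 22.6 ± 6.13 CPM with dihydromyricetin (-1.48 ± 0.27, adjusted p = 0.0342). Ryr2 rose by 3.74 ± 0.51, and Mettl24 (-1.58 ± 0.27), Scd1 (-1.40 ± 0.29) and Prune2 (-1.60 ± 0.46) fell. Each of these 4 genes is higher in adipocyte nuclei in ND, and Ryr2 stood at 323 CPM there in HFD. Between DHM_HFD and HFD, 22 endothelial genes rose and 78 fell. Svep1 (1.85 ± 0.27), Tmem267 (1.43 ± 0.30) and Mettl24 (1.30 ± 0.27) rose. In DHM_HFD, Svep1 stood at 1053 CPM in adipocyte against 109.3 in endothelial nuclei and Mettl24 at 105 against 12.2. Both also rose in adipocytes, so free adipocyte RNA may carry these 2 rises. Adamtsl4 (-1.62 ± 0.29) and the heat shock gene Hspa1b (30.9 ± 11.4 against 119 ± 15.7 CPM, -1.94 ± 0.32, adjusted p = 0.0220) fell. Hspa1a and Hspa1b are near-identical copies, so the split of counts between them is uncertain. The endothelial count of 1752 was 780 without ND replicate 1, 916 without ND replicate 3, 821 without HFD replicate 2 and 868 without HFD replicate 3. The count of 100 was 56 without ND replicate 2 or 3, 65 without HFD replicate 1 or DHM_HFD replicate 2, 10 without HFD replicate 2, 3 without HFD replicate 3, 254 by DESeq2 and 588 without the filter. Each of these 6 genes named between DHM_HFD and HFD lost its call without HFD replicate 2 and without HFD replicate 3. Prune2 lost its own without ND replicate 3, HFD replicate 2 or 3, or DHM_HFD replicate 1.

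In adipocyte progenitors, 340 of 12011 genes rose and 231 fell with the high-fat diet. The immediate early gene Arc (4.27 ± 0.67) and Thbs4, a thrombospondin gene (54.1 ± 43.9 against 2.53 ± 2.35 CPM, 4.24 ± 0.80), rose. The hedgehog-binding gene Hhip (-3.35 ± 0.65), Hmgcll1 (10.2 ± 6.06 against 54.4 ± 9.38 CPM, -2.43 ± 0.35, adjusted p = 0.00302) and Tex9 (-2.37 ± 0.34) fell. With dihydromyricetin, 51 rose and 57 fell. Hmgcll1 rose to 47.3 ± 16.7 CPM (2.22 ± 0.36, adjusted p = 0.0178), and Tmem267 (2.98 ± 0.52) and the cytokine-induced gene Cish (2.68 ± 0.58) rose too. Cish (87.7 against 26.2 CPM in progenitors) and Tmem267 (15.9 against 13.4) have higher levels in adipocyte nuclei in DHM_HFD and rose there too, so free adipocyte RNA may add to these rises. Thbs4 fell to 1.60 ± 0.262 CPM (-4.99 ± 0.88, adjusted p = 0.0255), as did the imprinted gene Rtl1 (-2.13 ± 0.28) and Peak1os (-2.04 ± 0.42). The first count, 571, was 172, 258 and 139 without ND replicates 1, 2 and 3, and 263, 237 and 165 without HFD replicates 1, 2 and 3. It was 1134 without DHM_HFD replicate 2, 1003 without DHM_HFD replicate 3 and 1232 without the filter. The second, 108, was 61, 45 and 42 without ND replicates 1, 2 and 3, and 40, 7 and 6 without HFD replicates 1, 2 and 3. It was 163 without DHM_HFD replicate 3, 236 by DESeq2 and 582 without the filter. Among the genes named, only Fosb, Arc, Hmgcll1 and Tex9 in the first comparison and Rtl1 in the second kept their calls with any single library left out.

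In pericytes, 258 of 10222 genes rose and 67 fell with the high-fat diet. Ryr2 rose by 3.56 ± 0.83, and Tmem132b (-4.50 ± 0.83), Slc35f3 (-2.48 ± 0.52) and the kinase gene Map2k6 (-1.75 ± 0.30) fell. Ryr2 (323 against 59.4 CPM in HFD) and Tmem132b (74.6 against 17.8 CPM in ND) have higher levels in adipocyte nuclei. Free adipocyte RNA, or doublets with adipocyte nuclei left in this class, may therefore carry these changes. Ryr2 lost its call without any ND replicate or HFD replicate 1 or 3, Slc35f3 without ND replicate 1 or 2 or HFD replicate 2 or 3, and Tmem132b without ND replicate 1. Hypoxia response genes (3 of 12 up, 9 not past; camera adjusted p = 2.46e-04, adjusted p = 0.121 with an estimated correlation) and glycolysis genes (2 of 18 up, 16 not past; 4.51e-04, and adjusted p = 0.388 with an estimated correlation) were higher. With dihydromyricetin only Hspa1a (14.0 ± 2.87 against 79.3 ± 17.1 CPM, -2.53 ± 0.32, adjusted p = 0.0123) and Hspa1b (-2.40 ± 0.36, adjusted p = 0.0440) changed, both lower. The count of 325 was 93, 163 and 117 without ND replicates 1, 2 and 3, 141 without HFD replicate 3 and 629 without DHM_HFD replicate 3. It was 694 without the filter, 780 with doublets kept and 571 without the 2 most loaded libraries. The count of 2 was 1 without ND replicate 2, HFD replicate 3 or DHM_HFD replicate 2, 0 without DHM_HFD replicate 1 and 183 without DHM_HFD replicate 3. It was 12 by DESeq2, 106 without the filter, 57 with doublets kept and 78 without the 2 most loaded libraries. DESeq2 gave no adjusted p for 8323 of the 10222 genes, Hspa1a and Hspa1b among them, so it does not speak for or against these 2. Hspa1b lost its call without ND replicate 2, HFD replicate 1 or 3, or DHM_HFD replicate 1 or 2, and Hspa1a without DHM_HFD replicate 1.

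In macrophages, 46 of 9250 genes rose and 10 fell with the high-fat diet. The finer clustering named a dendritic cluster, with 0.343, 0.267 and 0.409% of kept nuclei in ND, 0.318, 0.270 and 0.192% in HFD and 0.394, 0.146 and 0.203% in DHM_HFD. The main clustering named no such class, so the macrophage class may hold dendritic nuclei. Depp1, a target gene of FOXO factors, rose from 8.88 ± 0.269 to 46.4 ± 14.3 CPM (2.39 ± 0.40, adjusted p = 0.00935), and Sirpb1b fell from 48.8 ± 7.10 to 12.4 ± 5.08 CPM (-1.98 ± 0.36, adjusted p = 0.0157). Ryr2 (4.06 ± 0.61) and Gmpr (2.54 ± 0.47) rose and Mettl24 (-1.93 ± 0.38) and Acaa1a (-1.31 ± 0.27) fell, 4 genes with higher levels in adipocyte nuclei. With dihydromyricetin 4 genes changed. The fibronectin gene Fn1 fell from 160.4 ± 21.4 to 51.3 ± 7.47 CPM (-1.64 ± 0.25, adjusted p = 0.0272) and Adgrg6 from 376 ± 22.7 to 203 ± 13.7 CPM (-0.89 ± 0.15). Ehhadh (2.28 ± 0.33) and Slc1a3 (1.37 ± 0.23), both higher in adipocyte nuclei, rose. The count of 56 was 19, 26 and 21 without ND replicates 1, 2 and 3, 34 and 28 without HFD replicates 1 and 3 and 186 without DHM_HFD replicate 2. It was 102 by DESeq2, 333 without the filter and 222 with doublets kept. The count of 4 was 2 and 0 without ND replicates 1 and 2, 0 without HFD replicate 1, 2 or 3 or DHM_HFD replicate 3, 1 without DHM_HFD replicate 1 and 20 without DHM_HFD replicate 2. It was 28 by DESeq2, 89 without the filter and 14 with doublets kept. Of all the genes named here only Ryr2 kept its call with any single library left out.

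In Schwann cells, 30 of 3351 genes rose and 3 fell with the high-fat diet. Fos reached 140.3 ± 78.8 CPM with no count in ND (at least 13.7-fold over the group), and Egr1 rose from 10.1 ± 1.21 to 209 ± 193 CPM (4.28 ± 0.89). Schwann nuclei of the ND libraries held only 106827 to 139747 UMIs. The ND level of Egr1 therefore rests on very few UMIs, and the size of its fold is uncertain. Car3 (-2.22 ± 0.45) and Scd1 (-1.50 ± 0.30), genes with higher levels in adipocyte nuclei, fell. With dihydromyricetin, Nfatc1, which encodes a calcium-regulated transcription factor, fell from 236 ± 39.0 to 34.03 ± 8.87 CPM (-2.75 ± 0.41, adjusted p = 0.00402). Stk32a (-1.33 ± 0.26) and Fnip2 (-1.24 ± 0.24) fell too. So did the predicted genes Gm50469 (-2.54 ± 0.45) and Gm32880 (-2.23 ± 0.43), which are outside the naming rule and were chosen after their values were seen. The count of 33 was 0 and 11 without ND replicates 1 and 3, and 21, 13 and 9 without HFD replicates 1, 2 and 3. It was 53 and 110 without DHM_HFD replicates 2 and 3, 87 without the filter and 79 with doublets kept. The count of 5 was 3 without ND replicate 1 or HFD replicate 1, 1 without HFD replicate 2 or DHM_HFD replicate 2, 0 without HFD replicate 3, 2 without DHM_HFD replicate 1, 9 without DHM_HFD replicate 3 and 24 without the filter. Each gene named lost its call without at least 1 library, Fosb without ND replicate 1 and Nfatc1 without HFD replicate 3.

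Lymphocytes of the T or NK kind and smooth muscle cells gave few genes. In lymphocytes, Ryr2 (4.79 ± 0.85) and Rbfox1 (2.74 ± 0.52) rose with the high-fat diet. With dihydromyricetin Slc1a3 (3.53 ± 0.46), Svep1 (2.18 ± 0.34), Nrp1 (1.57 ± 0.30) and 4930438E09Rik (2.72 ± 0.53; outside the naming rule and chosen after its values were seen) rose. All 6 have higher levels in adipocyte nuclei, against 37.2% of tested genes. In smooth muscle, 4 genes rose and 3 fell with the high-fat diet. The phosphodiesterase gene Pde10a rose from 379 ± 190 to 1083 ± 122 CPM (1.53 ± 0.31), as did Safb2 (1.84 ± 0.36) and Btbd9 (1.84 ± 0.36). Car3 (-2.06 ± 0.28), Scd1 (-1.63 ± 0.31) and Mir99ahg (-1.46 ± 0.27), all higher in adipocytes, fell. With dihydromyricetin Svep1 (2.96 ± 0.43) and the activin receptor gene Acvr1c (1.76 ± 0.32) rose, both higher in adipocytes. Of the smooth muscle genes, Car3 and Svep1 kept their calls with any single library left out. Pde10a, Safb2, Btbd9, Scd1 and Mir99ahg each lost theirs without ND replicate 3, HFD replicate 2 or HFD replicate 3 and under the replicate block. Acvr1c lost its own without any HFD replicate or DHM_HFD replicate 1 or 3 and under the block. In lymphocytes Ryr2 and Rbfox1 lost theirs without ND replicate 1 or 3 or HFD replicate 1 or 3, among others. Svep1 lost its call without HFD replicate 3, and Nrp1 without 7 of 9 libraries. The lymphocyte count of 2 was 0 without ND replicate 1 or 3 or HFD replicate 1 or 3, 5 without ND replicate 2, 25 without HFD replicate 2, 1 without DHM_HFD replicate 3, 28 without the filter and 20 with doublets kept. The count of 4 in lymphocytes was 2 without ND replicate 1, HFD replicate 2 or any DHM_HFD replicate, 1 without HFD replicate 3 and 11 without the filter. The smooth muscle count of 7 was 2 and 1 without ND replicates 1 and 3, 11 without ND replicate 2 or HFD replicate 1, 1 without HFD replicate 2 or 3, 16 without DHM_HFD replicate 2 and 22 without the filter. The count of 2 in smooth muscle was 1 without any HFD replicate or DHM_HFD replicate 1 or 3, 41 without DHM_HFD replicate 2 and 24 without the filter.

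No share of a class differed between groups by the exact test: over 36 tests the smallest p was 0.100, the smallest possible with 3 against 3 libraries, and the smallest adjusted p 0.720. Smooth muscle nuclei made up 0.353 ± 0.0147% of kept nuclei in ND, 0.379 ± 0.0472% in HFD and 0.520 ± 0.0513% in DHM_HFD, with the 3 DHM_HFD libraries above the other 6. By edgeR on the numbers of nuclei they differed between DHM_HFD and HFD at an unadjusted p of 0.0163 (adjusted p = 0.294) and from ND at 0.00520 (adjusted p = 0.187). Lymphocytes of the T or NK kind made up 0.697 ± 0.532, 0.358 ± 0.0878 and 0.271 ± 0.0368%, and adipocyte progenitors 5.15 ± 0.434, 4.42 ± 0.744 and 4.64 ± 0.284%. The lymphocyte share in ND rests on replicate 3, at 1.30% against 0.470 and 0.317%. Without it the difference of HFD from ND went from -0.339 to -0.0351 points and that of DHM_HFD from -0.427 to -0.123. Macrophages made up 2.56 ± 0.679, 2.21 ± 0.624 and 2.10 ± 0.399%. The adipocyte share was 2.06 points lower in DHM_HFD than in HFD and 0.382 points higher without HFD replicate 3. The endothelial share was 1.55 points higher, and 1.42 points lower without DHM_HFD replicate 2. Sorting and the release of nuclei act on these shares, so they describe the nuclei recovered.

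**Figure D5:**
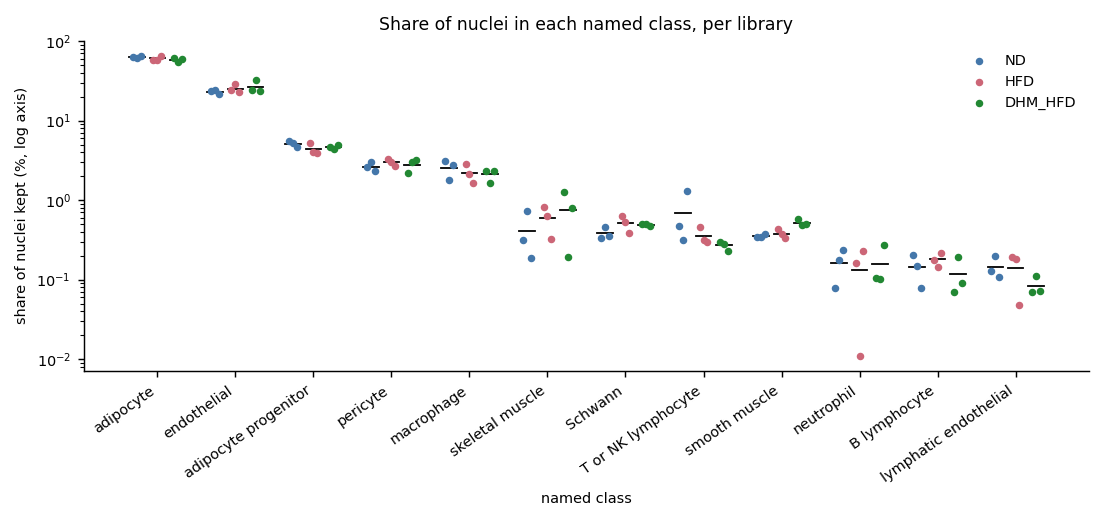
Share of kept nuclei (%, log axis) in each of 12 named classes. Points are libraries coloured by group and short lines are means of 3; smooth muscle is at 0.353, 0.379 and 0.520% in ND, HFD and DHM_HFD.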

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

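The alternatives without the 2 libraries of most barcodes (HFD replicate 1 and DHM_HFD replicate 3) and without 3 adipocyte clusters were chosen only after the results had been seen, and the others were fixed before. Of the 56 called genes named in adipocyte nuclei for HFD against ND, 52 kept direction and call in every alternative run and with any single library left out. For DHM_HFD against HFD this held for 6 of 31 (Zbtb16, Aldh1a1, Igfbp5, Tsc22d3, Eya2 and Mettl24), and for 18 of 20 for DHM_HFD against ND. The alternative without genes over 5 times higher in another class held only 41, 21 and 11 of these called genes, in the same order. The rest, Aldh1a1, Igfbp5 and Eya2 among them, are that much higher in another class and were judged on the other alternatives alone. Whether free RNA of other classes carries their changes was not tested. No called named gene turned its direction. With 1 library left out, a group of 2 remains and its spread is pooled with that of the other groups. For each count below that moved, the cause was not tested, apart from the smaller number of samples where libraries were left out. Depth limits the classes with few nuclei most: only 2471 genes in lymphocytes and 3351 in Schwann cells passed the filter on low counts, against 20211 in adipocytes.

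With single libraries left out, counts of changed genes for HFD against ND ranged from 2710 to 5580 in adipocytes, 780 to 2278 in endothelial cells, 139 to 1134 in progenitors, and 93 to 629 in pericytes. They ranged from 19 to 186 in macrophages, 0 to 110 in Schwann cells, 0 to 25 in T or NK lymphocytes and 1 to 16 in smooth muscle. For DHM_HFD against HFD they ranged from 46 to 517, 3 to 106, 6 to 163, 0 to 183, 0 to 20, 0 to 9, 1 to 4 and 1 to 41 in the same order. Adipocyte genes ranged from 1567 to 3320 for DHM_HFD against ND, genes of opposite change from 38 to 318 and lists for DHM_HFD against HFD from 2 to 6. Where edgeR counts fell to 0 with a library left out, the full set of libraries had 421 genes at an unadjusted p under 0.05 and 27 by DESeq2 in Schwann cells, 245 and 7 in lymphocytes (HFD against ND). For DHM_HFD against HFD it had 301 and 6 in Schwann cells, 749 and 28 in macrophages and 822 and 12 in pericytes.

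Without the 2 libraries of most barcodes, adipocyte counts were 2859 (HFD against ND), 14 (DHM_HFD against HFD) and 1397 (DHM_HFD against ND), with 12 genes of opposite change and 1 list for DHM_HFD against HFD. Pericytes had 571 and 78 genes for HFD against ND and DHM_HFD against HFD, and smooth muscle 18 and 1. Lymphocytes had 0 for HFD against ND and macrophages 0 for DHM_HFD against HFD. By DESeq2, counts for DHM_HFD against HFD were 951 in adipocytes, 236 in progenitors, 254 in endothelial cells, 28 in macrophages, 12 in pericytes and 5 in smooth muscle. By the same test HFD against ND gave 7 in lymphocytes and 102 in macrophages, and 568 genes changed in opposite directions. Without the filter on low counts, HFD against ND and DHM_HFD against HFD gave 87 and 24 genes in Schwann cells, 28 and 11 in lymphocytes, and 1232 and 582 in progenitors. The same 2 gave 333 and 89 in macrophages, 694 and 106 in pericytes and 22 and 24 in smooth muscle. DHM_HFD against HFD gave 1374 in adipocytes and 588 in endothelial cells, and opposite changes were 806. With doublets kept, the same 2 comparisons gave 79 and 12 genes in Schwann cells, 222 and 14 in macrophages and 780 and 57 in pericytes, and HFD against ND gave 20 in lymphocytes. Without genes that are over 5 times higher in another class, counts were 56 in Schwann cells and 1 in lymphocytes for HFD against ND. For DHM_HFD against HFD they were 185 in endothelial cells, 15 in macrophages and 6 in pericytes. The stricter nucleus filter gave 2 in macrophages for DHM_HFD against HFD. With an estimated correlation, 0 lists passed in either comparison, and fry called 2 and 0.

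Replicate numbers do not pair the adipocyte libraries, where those of the same number had correlations of their deviations from -0.106 to 0.0416. For the same number they ran from -0.0599 to 0.206 in Schwann cells, -0.00942 to 0.185 in macrophages and -0.199 to 0.265 in pericytes. Libraries of unlike number reached 0.104, 0.129 and 0.389 in the same order. Pairing stays open in Schwann cells and macrophages. In pericytes the highest value joined HFD replicate 1 and DHM_HFD replicate 3, so pairing by number is not shown there. Progenitors and endothelial cells reached 0.146 and 0.126 for the same number, and 0.330 and 0.279 for unlike numbers. With a replicate block, counts for HFD against ND and DHM_HFD against HFD were 105 and 13 in Schwann cells, 176 and 17 in macrophages and 1 and 1 in smooth muscle. DHM_HFD against HFD gave 10 in pericytes. The other gene counts stayed within 1.5 times of those without it. Under the block, Ucp1 stood at 0.0659 between DHM_HFD and HFD and Prdm16 at -0.0178 between DHM_HFD and ND.

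Some values that passed no test changed sign, and the cause was not tested. Without the filter Ucp1 stood at 0.00149 between DHM_HFD and HFD. Without the 2 libraries of most barcodes, Pparg stood at 0.0162 and Pnpla2 at -0.00820 between HFD and ND, and Pck1 at -0.0116 between DHM_HFD and HFD. With single libraries left out, log2 changes between HFD and ND ranged from -0.57 to 0.0489 for Ppargc1a, -0.15 to 0.00727 for Pparg and -0.40 to 0.24 for Dio2. They ranged from -1.13 to 0.0525 for Elovl3 and -0.0861 to 0.16 for Pnpla2. Between DHM_HFD and HFD they ranged from -0.23 to 0.29 for Ucp1 and -0.00448 to 0.29 for Ppargc1a. Between DHM_HFD and ND they ranged from -0.44 to 0.18 for Ppargc1a, -0.23 to 0.11 for Prdm16 and -0.29 to 0.89 for Elovl3. The difference in share between DHM_HFD and HFD ranged from -3.54 to 0.382 points for adipocytes, -1.42 to 3.43 points for endothelial cells and -6.61 to 5.07 points for adipocyte nuclei with a Ucp1 UMI.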

Other observations

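Of the tests in this part, those of splits for gene lists and opposite changes and that of genes particular to the mixed clusters were written before their results. The camera tests of the 31 lists were fixed before the data were examined, but the lists printed here were picked after the results had been seen. All other tests were chosen after that too. By camera, mitochondrially encoded genes as a list were lower in DHM_HFD than in HFD beyond adipocytes. With an estimated correlation this held in none of the classes below. Since sorted nuclei were sequenced, these UMIs may be free RNA that all classes of a library share, which was not tested. In progenitors the median log2 change of 11 genes was -0.58, with 0 past the test and 9 lower adjusted over the list alone (camera adjusted p = 9.40e-07, adjusted p = 0.599 with an estimated correlation). In macrophages it was -0.60 over 10 genes (5 lower adjusted over the list alone; 2.33e-05, and adjusted p = 0.879 with an estimated correlation). In endothelial cells it was -0.47 over 12 genes (2 lower adjusted over the list alone; 3.84e-04, and adjusted p = 0.882 with an estimated correlation). The same list stood at -0.66 over 6 genes in Schwann cells (9.72e-04, and adjusted p = 0.845 with an estimated correlation) and -0.33 over 10 genes in pericytes (0.0125, and adjusted p = 0.723 with an estimated correlation). The median share of mitochondrial UMIs per nucleus in whole libraries was 1.06, 0.733 and 0.660% in HFD and 0.448, 0.572 and 0.623% in DHM_HFD. The gap leans on HFD replicate 1, and HFD replicate 3 lay close to DHM_HFD replicate 3.

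The unfolded protein response was higher in HFD than ND in progenitors, with 5 of 18 genes up, 0 down and 13 not past the test (11 up adjusted over the list alone; camera adjusted p = 3.92e-05, adjusted p = 0.265 with an estimated correlation). It was lower in DHM_HFD than HFD, with 1 down and 17 not past the test (6 down adjusted over the list alone; 4.04e-04, and adjusted p = 0.667 with an estimated correlation). In pericytes 4 of 17 rose and 13 did not pass (9.09e-04, and adjusted p = 0.312 with an estimated correlation). In macrophages, 1 of 12 matrix and fibrosis genes fell in DHM_HFD, which was Fn1, and 11 did not pass (8 down and 1 up adjusted over the list alone; 2.33e-05, and adjusted p = 0.0663 with an estimated correlation).

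Some genes known to respond to glucocorticoids rose in HFD in several cell types. Fkbp5 stood at 124 against 55.9 CPM in adipocytes, 361 against 115 in endothelial cells, 764 against 487 in progenitors, 224 against 127 in pericytes and 829 against 302 in macrophages (adjusted p = 0.00147, 1.82e-05, 0.0436, 0.0207 and 0.00323). In endothelial cells Fkbp5 (-1.19), Zbtb16 (-1.08) and Tsc22d3 (-0.78) fell in DHM_HFD. Free adipocyte RNA as the source of the Fkbp5 rise is argued against in 4 of 4 other classes, where the smallest rise would need more adipocyte RNA than the highest adipocyte marker shows. For Zbtb16 and Tsc22d3 this held in only 3 of 8 pairs of gene and class. In pericytes the smallest rise of Tsc22d3 was -21.1 CPM, so its HFD and ND libraries overlapped there. Time of day at collection stays open, since the clock list also differed between HFD and ND and stood at a median of -0.26 between DHM_HFD and HFD (camera adjusted p = 0.0519). A higher glucocorticoid exposure in HFD is a hypothesis. Of the other genes of such a list, 10 of 20 rose between HFD and ND in adipocytes, 9 of 20 in endothelial cells, 7 of 20 in progenitors and 4 of 18 in pericytes, with 1 down in each, and 1 of 17 in macrophages with 0 down. Camera passed in all 5 (adjusted p = 4.03e-04, 1.71e-04, 6.97e-06, 2.85e-04 and 5.92e-05), but none held with an estimated correlation (adjusted p = 0.212 for each). By fry pericytes (adjusted p = 0.0703) and macrophages (adjusted p = 0.0713) did not pass. Between DHM_HFD and HFD these genes went both ways, with 10 of 20 above 0 in adipocytes, 9 of 20 in endothelial cells, 8 of 20 in progenitors, 8 of 18 in pericytes and 6 of 17 in macrophages. Their medians (from -0.14 to -0.01) passed in none and decide nothing. Hormone levels were not analysed here.

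Clusters 7 and 15 carry adipocyte and endothelial markers together, as the labels' hybrid adipose-endothelial cells would. They hold 5723 nuclei before removal of doublets, 3.82 ± 0.50, 4.83 ± 1.82 and 6.46 ± 3.11% of passing nuclei in ND, HFD and DHM_HFD, and 63.6% of them were marked as doublets. Of 9548 genes, 0 exceeded every named class by 2 times in the nuclei not marked. This argues against a cell type with genes of its own as the main part of these nuclei. It cannot decide on a small part, whose genes would be diluted by doublets left unmarked. Their profile matched a mixture of 73.0% adipocyte and the rest endothelial RNA with a correlation of 0.995 across genes (genes are not independent replicates), so doublets and a cell with both sets of genes cannot be told apart. The share rose with the number of barcodes per library (Pearson r = 0.904, permutation p = 0.0217; Spearman rho = 0.5, permutation p = 0.178; 9 libraries). Without DHM_HFD replicate 3 and HFD replicate 1, r was -0.334 (exact p = 0.435), so the relation rests on those 2 libraries.

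In pericytes, a split that parts HFD replicates 1 and 3 and DHM_HFD replicate 3 from the other 3 libraries called 753 genes, 533 higher and 220 lower, against 2 for the real groups, which points to a structure of the samples. Adipocyte RNA in pericyte nuclei may account for it: 98.3% of the higher genes and 0% of the lower are higher in adipocytes, against 47.5% of 10222 tested. In the finer clustering, a cluster with pericyte and adipocyte markers together held 1.33, 0.146 and 0.636% of kept nuclei in HFD replicates 1 to 3. It held 0.255, 0.191 and 1.61% in DHM_HFD and 0.441, 0.317 and 0.428% in ND. Of its nuclei, 48.4% were marked as doublets. The main clustering did not set such nuclei apart, so unmarked doublets may lie in the pericyte class. Adipocyte markers in pericytes reached 24.0, 17.3 and 22.1% of their adipocyte level in ND, 31.0, 13.5 and 27.3% in HFD and 13.1, 10.4 and 33.3% in DHM_HFD. Whether the number of barcodes sets this stays open, with Pearson r = 0.760 (permutation p = 0.0144), Spearman rho = 0.583 (permutation p = 0.108) and r = 0.255 (exact p = 0.587) without DHM_HFD replicate 3 and HFD replicate 1. Both relations with barcodes form a family of 2, with Benjamini-Hochberg adjusted p = 0.0217 for each. No biological explanation was tested.

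The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. In adipocytes, 1 of 10 splits, the real one, gave as many genes in each comparison: 4588, 350 and 2986 genes for HFD against ND, DHM_HFD against HFD and DHM_HFD against ND. Any other split gave at most 0. Each other split mixes the groups, so a difference between the groups itself widens the spread within each side and lowers the count. The 0 is therefore no measure of the count expected without a difference, here or in the other classes. The 235 opposite changes also stood against at most 0, which adds nothing, since splits without a called gene can hold no opposite change. For gene lists, 3 splits gave as many as the real 9 between HFD and ND, with up to 12 in another split. Between DHM_HFD and HFD, 2 gave as many as the real 5, with up to 8. For HFD against ND the real split and the highest other gave 1752 and 0 genes in endothelial cells, 571 and 0 in progenitors, 325 and 0 in pericytes, 56 and 0 in macrophages, and 33 and 0 in Schwann cells. They gave 7 and 1 in smooth muscle, and 2 and 3 in lymphocytes, where 3 splits gave as many. For DHM_HFD against HFD they gave 100 and 1, 108 and 0, 2 and 753, 4 and 3, 5 and 5, 2 and 1, and 4 and 0 in the same order, with 2 splits as large in pericytes and in Schwann cells.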
